A study of Rattus norvegicus with 4 samples.

How the data were processed

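The series measured polyadenylated RNA of S16 rat Schwann cells in 4 libraries, 2 transfected with a control siRNA and 2 with siRNAs against Nr2f1 and Nr2f2, per the labels. Cells were lysed in Trizol and the purified RNA was poly-A selected, fragmented, primed with random hexamers and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Groups were taken from the labels. The columns of the deposited tables name the group. They also carry the numbers 3 and 1 for control libraries A and B and 3 and 2 for siRNA libraries A and B, which do not match the replicate numbers in the sample titles and whose meaning is not given in the sources used here. Libraries are therefore called A and B in the order of the columns, and whether those numbered 3 share a well or a day is not known.

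The deposited count table holds whole-number read counts per Ensembl rat gene, made with HISAT2, featureCounts 1.5.0-p3 and DESeq2 1.20.0 among the tools per the submitters' processing notes, which do not say which tool made which values. The genome build, the annotation release and whether counting used strand are not given in the sources used here, so reads of genes that overlap on opposite strands may have been counted together. Coordinates are those in the deposited files. The count table listed 32545 genes, of which 18598 had a count in any library and 13947 had none, and every entry named a gene. The authors' deposited comparison table lists 17633 genes; the 14912 genes left out of it have at most 1 count in total. Its per-library signal values are read counts divided by one size factor per library, by the authors, with size factors of 0.915 and 0.759 for control libraries A and B and 0.931 and 1.56 for siRNA libraries A and B. The log2 fold changes and the p-values in the same table are the authors' deposited results, and 5470 of its adjusted p-values are exactly 1. The table also holds 8 columns of counts and FPKM values per library, deposited by the authors, which were not used here. Protein-domain family names were read from an annotation column of the deposited count table.

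Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr on the groups (13018 genes), libraries were scaled by TMM (factors 0.975 and 0.990 for control libraries A and B, 1.02 and 1.02 for siRNA libraries A and B), and a quasi-likelihood model with an intercept and the group was fitted with robust dispersion. The biological coefficient of variation was 0.111. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are counts scaled by library size and TMM factor, and each mean has an SD over the 2 libraries of its group. Scaled by library size alone, without the TMM factor, 3 counts correspond to 0.139 CPM in the shallowest library and to 0.0697 CPM in the deepest. For genes resting on few counts, the ratio of summed counts is given with its exact Clopper-Pearson 95% interval; reads carried no molecular identifiers, so these intervals cover counting error only. No other technical split of the libraries was given by the labels. Mitochondrial genes held 4.25% and 3.63% of the counts in control libraries A and B and 4.05% and 4.70% in siRNA libraries A and B, and the 10 most abundant genes held 7.81%, 7.38%, 7.84% and 8.15%.

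In total, 24 gene lists were fixed before the data were examined, for myelin and Schwann cell states, lipid synthesis, matrix, signalling pathways, nuclear receptors, cell cycle, stress and inflammation, and markers of other cell types. Some genes are in more than one list, among them Hey2, Rarb, Vegfa, Col1a1 and Col3a1. Lists with at least 5 tested members were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over all lists, beside camera with an estimated correlation and fry. With an estimated correlation camera takes its degrees of freedom from the libraries. With 2 libraries per group it can therefore detect little, and a list that it does not call is not thereby shown to be unchanged. Where several gene IDs share a symbol, the ID with the most counts stood for the list member. Members were counted at the threshold over all tested genes and, separately, adjusted over the list alone.

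Genes to name were also set by a rule before the data were examined. They are Nr2f1, Nr2f2 and the paralog Nr2f6; the 12 largest rises and the 12 largest falls among called protein-coding genes with a symbol, at least 5 CPM in the higher group and no overlap between the groups; up to 4 members with the smallest adjusted p in each list, or the 2 most abundant where no member passed; and the 4 most abundant called genes with at least a 2-fold change. The rule named 111 genes, of which 108 passed the test, and 6 of them overlap another gene with at least 20 counts. Other genes named were chosen after their values were seen. The values of 1 gene named by the rule, and 1 test of the neighbouring genes on chromosome 1, are not reported here. In 1 case a gene ID without counts shares a named gene's symbol.

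The count test was tested on simulated counts for the same 13018 genes, 2 simulated libraries against 2, with 200 changed genes in each of 5 simulations. With dispersions drawn along the fitted trend it called 45.6% of genes changed by 0.5 on the log2 scale, 75.9% of those changed by 1 and 93.0% of those changed by 2, and 4.58% of its calls were unchanged genes. With dispersions drawn gene by gene 13.0% of its calls were unchanged genes. Far fewer genes were changed in each simulation than the 2350 called in the data. The adjustment depends on that share, so these rates may not carry over to the data. Camera called the shifted list of 20 genes, moved by 0.7, in 5 of 5 simulations and 0 of 100 unchanged lists at an unadjusted p under 0.05. The simulated genes varied independently of each other and the unchanged lists were random genes. These simulations therefore do not show how often camera calls unchanged lists whose genes are correlated.

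The alternatives set before the data were examined were DESeq2 size factors, upper-quartile and library-size scaling; no filter on low counts, or at least 1 CPM in 2 libraries; the DESeq2 1.42.0 Wald test, limma-voom and edgeR's older quasi-likelihood method; protein-coding genes alone; stricter thresholds; other set tests; and leaving out each library in turn. Thinning of all libraries to the shallowest total and loess offsets of the log count against mean expression were chosen after seeing the data. Family enrichment used a hypergeometric test and was repeated without the members of the cell cycle list, a choice made after seeing the data. Shuffles of gene positions, which treat genes as independent in position, were drawn from a fixed seed. They were applied first to the lowest median of a window and then, after that result had been seen, to the count of genes at least 2-fold lower in a window. These steps used python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.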

Results

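Polyadenylated RNA was sequenced from S16 cells, a rat Schwann cell line, after transfection with a non-targeting control siRNA or with siRNAs against Nr2f1 and Nr2f2. These genes encode the orphan nuclear receptors COUP-TFI and COUP-TFII. Each of the 2 groups held 2 libraries, called A and B here in the order of the deposited columns. The column names carry a number of unstated meaning, 3 for library A of both groups, 1 for control library B and 2 for siRNA library B. Whether any libraries were paired in the experiment is not known, and the fit used no pairing. Counts assigned to genes totalled 26561522 and 21556011 in control libraries A and B, and 25618234 and 43057750 in Nr2f1/Nr2f2 siRNA libraries A and B. The deepest library had 13654 genes with at least 10 counts and the shallowest had 12649. Libraries of the same group differed by more than counting noise, with a chi-square of 12.3 per gene in the control group and 12.3 in the siRNA group. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Unless another test is named, adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and fold changes are Nr2f1/Nr2f2 siRNA over control siRNA. Levels are TMM-scaled CPM, given as mean ± SD with n = 2.

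Both targeted transcripts fell in the siRNA libraries. Nr2f1 fell from 216.8 ± 12.2 to 58.7 ± 3.84 CPM, a log2 fold change of -1.89 (SE 0.09, adjusted p = 4.49e-08), which left 27.0% of the control level. Nr2f2 fell from 288.7 ± 9.78 to 70.4 ± 3.21 CPM, a log2 fold change of -2.03 (SE 0.08, adjusted p = 1.35e-08), which left 24.4% of the control level. In each library the values matched the label. Nr2f1 was at 225 and 208 CPM in the control libraries and at 61.4 and 56.0 CPM in the siRNA libraries, and Nr2f2 at 296 and 282 CPM against 68.1 and 72.6 CPM. The paralog Nr2f6, which the siRNAs were not labelled to target, was at 102.3 ± 8.27 CPM in control and 115.3 ± 15.4 CPM in siRNA libraries. This difference did not pass the test (log2 fold change 0.17, SE 0.10, adjusted p = 0.278). Coordinates are those of the deposited files, whose genome build is not given in the sources used here. Nr2f1 (ENSRNOG00000014795) lies on chromosome 2 from 5570008 to 5579894 and Nr2f2 (ENSRNOG00000010308) on chromosome 1 from 131448447 to 131460473, both as protein-coding genes on the minus strand.

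**Figure D1:**
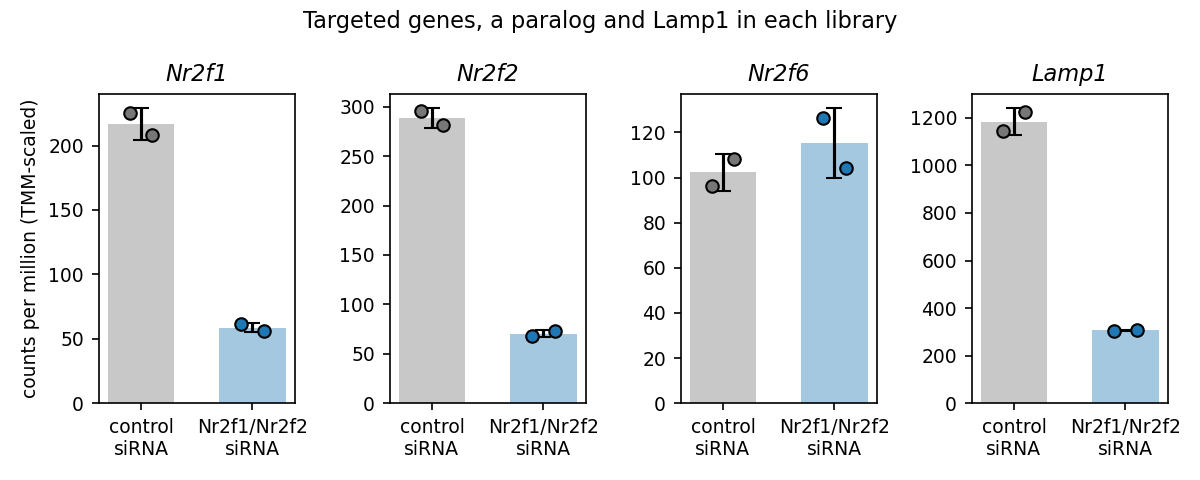
CPM, TMM-scaled, of Nr2f1, Nr2f2, the paralog Nr2f6 and Lamp1 in the control siRNA and Nr2f1/Nr2f2 siRNA libraries; points are the 2 libraries of a group, bars their mean and error bars the SD. The siRNA libraries hold 27.0% of the control level of Nr2f1 and 24.4% of that of Nr2f2, and for Nr2f6 the means are 102.3 and 115.3 CPM.

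The comparison asks which transcripts of S16 cells differ when Nr2f1 and Nr2f2 are lowered together. Many genes passed the test and most changes were small. Of 13018 tested genes, 2350 (18.1%) had an adjusted p under 0.05, with 1048 higher and 1302 lower in the siRNA libraries. The median absolute log2 fold change of these genes was 0.47, and 87.7% of them changed less than 2-fold. There were 175 genes at least 2-fold higher and 114 at least 2-fold lower. All of the 2350 genes had both siRNA libraries on the same side of both control libraries, as did 58.6% of all tested genes, where chance gives 33.3% for 2 libraries against 2. Passing the test nearly requires such a separation, so it adds no support to the calls. Genes of a library can shift together, so the 58.6% is not a test against 33.3%. Weakly expressed genes had higher fitted values, with a median log2 fold change of 0.19 over the 1237 genes at or below 1 CPM and 0.12 over the 2919 genes above that and up to 10 CPM. The median was -0.00 over the 6642 genes above 10 and up to 100 CPM, and -0.06 over the 2220 genes above 100 CPM. In a multidimensional scaling of the libraries the first axis (46.8% of the variance) separated the groups, and the next (28.9%) separated control library A at -0.89 from control library B at 0.93. With scaling by library size alone in place of TMM, 1381 genes were higher and 1009 lower, so that 57.8% of the called genes were higher against 44.6% with TMM. Library-size scaling raised the median log2 fold change of all tested genes by 0.052 and upper-quartile scaling raised it by 0.034, with nearly the same shift for every gene. Without control library A, 1553 genes passed (611 higher and 942 lower), and without siRNA library B 1353 passed (602 higher and 751 lower).

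**Figure D2:**
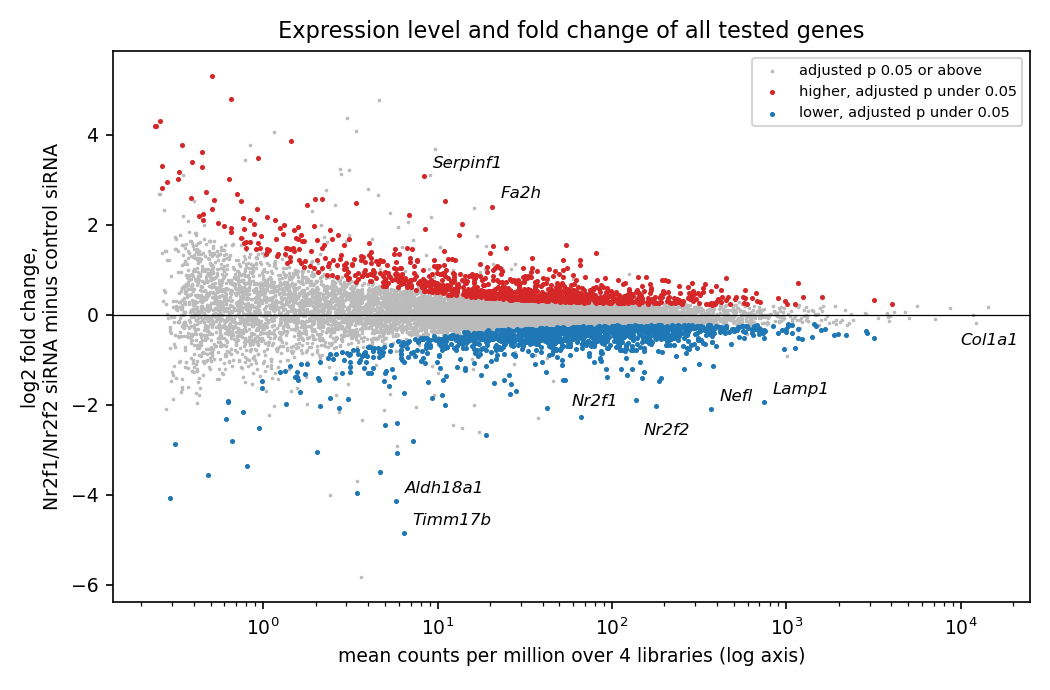
Log2 fold change, Nr2f1/Nr2f2 siRNA minus control siRNA, of the 13018 tested genes against their mean CPM over the 4 libraries on a log axis; red points are the 1048 genes that were higher and blue points the 1302 that were lower with an adjusted p under 0.05, and grey points did not pass. Lamp1 and Nefl stand out among abundant transcripts, at -1.95 and -2.10.

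Among called protein-coding genes with at least 5 CPM in the higher group, Serpinf1 rose most. Serpinf1, which encodes the secreted factor PEDF, rose from 1.77 ± 0.151 to 15.0 ± 2.12 CPM (log2 fold change 3.07, SE 0.22, adjusted p = 2.3e-06). Sts, encoding steroid sulfatase, rose by 2.53 on the log2 scale (SE 0.18, adjusted p = 2.93e-06). Fa2h, whose enzyme hydroxylates the fatty acids of myelin sphingolipids, rose from 6.49 ± 0.105 to 34.4 ± 4.38 CPM (log2 fold change 2.40, SE 0.14, adjusted p = 6.2e-07). Cyp26b1, which encodes an enzyme that degrades retinoic acid, rose by 2.22 (SE 0.20, adjusted p = 2e-05). The other large rises on the log2 scale were in Tm4sf1 (2.48), Anxa8 (2.02), Fam107a (1.90), the calcium pump gene Atp2b4 (1.77), the claudin gene Cldn14 (1.59), Chadl (1.54), the collagen gene Col11a2 (1.52) and Slitrk6 (1.47).

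The largest fall by the same criteria was in Timm17b (-4.86, SE 0.65, adjusted p = 0.014), which encodes a subunit of the mitochondrial import machinery. Aldh18a1, encoding an enzyme of proline synthesis, fell by 4.14 on the log2 scale (SE 0.27, adjusted p = 1.36e-06). Tktl1 (-3.97), Rmnd5b (-3.49), Nfs1 (-3.07), the gene of the cysteine desulfurase of iron-sulfur cluster assembly, and Tspan18 (-2.67) fell as well. So did the guanylate-binding protein gene Gbp5 (-2.45), Wnt11 (-2.40), the neurofilament gene Nefl (-2.10) and the extracellular protease genes Adamts15 (-2.28) and Adamts9 (-2.07). The 4 most abundant genes that changed at least 2-fold all fell. Lamp1, which encodes a major lysosomal membrane protein, fell from 1184 ± 56.6 to 305.6 ± 1.90 CPM (log2 fold change -1.95, SE 0.07, adjusted p = 1.35e-08), and Nefl fell from 600.2 ± 72.8 to 140.3 ± 1.94 CPM. The sphingosine-1-phosphate receptor gene S1pr3 fell from 521.5 ± 16.7 to 234.7 ± 3.63 CPM and Egfl8 from 429.2 ± 34.2 to 201.4 ± 23.2 CPM. Egfl8 overlaps C4a on the same strand and Agpat1 on the other strand, so its values are uncertain. Aldh18a1 has a near copy, AC096370.2, that fell too (-2.80, SE 0.22), and how reads were split between them is uncertain. Timm17b rested on 566 counts in the control libraries against 29 in the siRNA libraries, a rate ratio of 0.0346 (95% exact interval 0.0230 to 0.0503, counting error only), and Tktl1 on 308 counts against 29. Timm17b lost its call without siRNA library A (adjusted p = 0.176) and without siRNA library B (adjusted p = 0.256), and was at -4.27 without control library B. It was also not called by limma-voom or without the filter on low counts. Without siRNA library B Tspan18 lost its call (adjusted p = 0.0685), Tktl1 was at -5.37 and Nfs1 at -4.40.

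**Figure D3:**
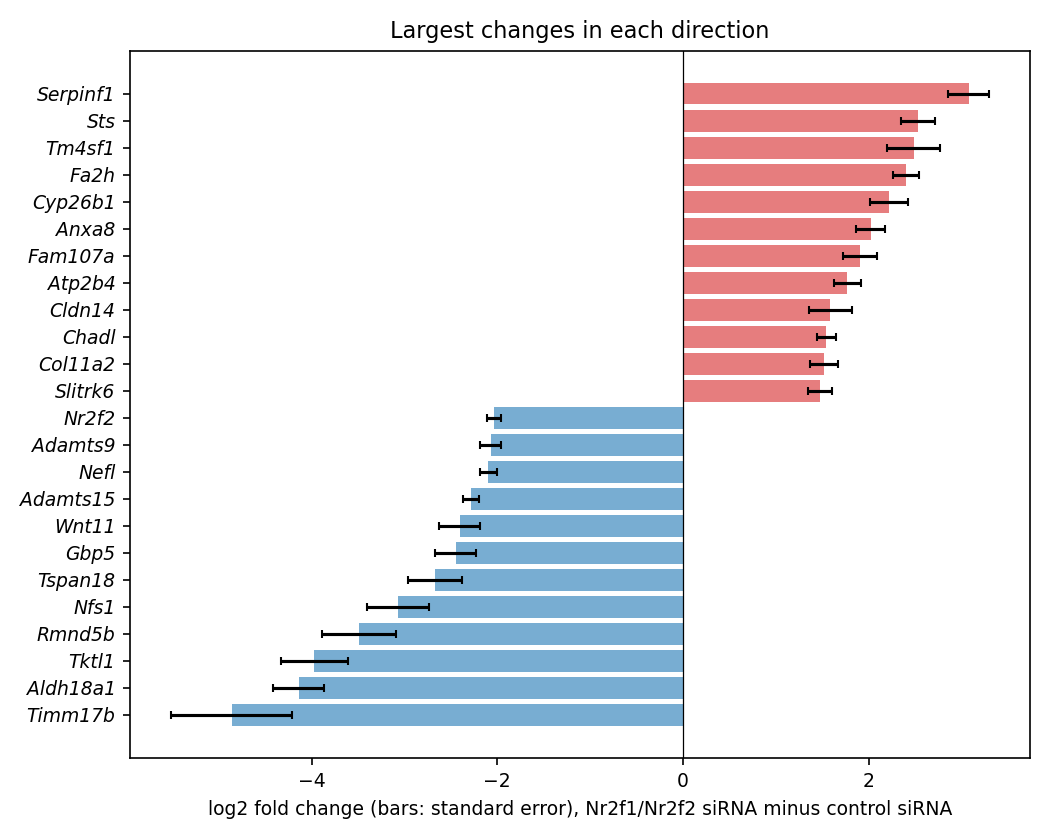
Log2 fold change, Nr2f1/Nr2f2 siRNA minus control siRNA, of the 12 genes with the largest rise and the 12 with the largest fall among called protein-coding genes with at least 5 CPM in the higher group; error bars are standard errors. Values run from 3.07 for Serpinf1 to -4.86 for Timm17b.

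Genes of the myelin sheath moved in both directions, more of them upwards. Of 20 tested peripheral myelin genes, 8 rose, 3 fell and 9 did not pass, and adjusted over the list alone 9 were higher and 5 lower. Besides Fa2h, the connexin gene Gjc3 (log2 fold change 0.91, SE 0.13) and Dusp15 (1.03, SE 0.11) rose. Pmp2, which encodes a fatty acid binding protein of myelin, fell from 449.4 ± 23.3 to 295.5 ± 15.6 CPM (-0.60, SE 0.08, adjusted p = 0.000214). The list as a whole was higher by camera with a preset correlation of 0.01 (adjusted p = 0.0386 over 24 lists; adjusted p = 0.554 with an estimated correlation). That call was lost when any 1 library was left out, with an adjusted p = 0.128 without control library A, 0.0585 without control library B, 0.154 without siRNA library A and 0.0655 without siRNA library B, when 5 members were higher. It was also lost with limma-voom (adjusted p = 0.141), with a filter of 1 CPM in 2 libraries (0.0754) and with counts thinned to the shallowest library (0.0671). Of 17 pro-myelinating regulators, 1 rose, 3 fell and 13 did not pass (list adjusted p = 0.483; adjusted over the list alone, 2 higher and 3 lower). The genes of the transcriptional coactivator Taz, Wwtr1 (-0.31, SE 0.07), of its partner Tead1 (-0.51, SE 0.07) and of the receptor Adgrg6 (-0.39, SE 0.07) fell, and Lgi4 rose (0.35, SE 0.07). Lgi4 overlaps Fxyd3 on the other strand and lost its call without siRNA library A (adjusted p = 0.0627), when 0 regulators were higher, while 2 were with library-size or loess scaling. Wwtr1 lost its call without siRNA library A (adjusted p = 0.0609) or B (adjusted p = 0.0799).

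Negative regulators of myelination mostly fell where they passed the test. Of 12 tested, 1 rose, 4 fell and 7 did not pass (list adjusted p = 0.0622; adjusted over the list alone, 1 higher and 5 lower). The list was called lower without control library A (adjusted p = 0.0222), without siRNA library A (0.0306) and without the filter on low counts (0.0210), all with the preset correlation; with all 4 libraries the adjusted p = 0.554 with an estimated correlation. Id2, the gene of an inhibitor of basic helix-loop-helix factors, fell from 17.8 ± 5.58 to 4.31 ± 0.844 CPM (log2 fold change -2.02, SE 0.25, adjusted p = 0.00128). The Notch effector gene Hey2 fell by 1.75 on the log2 scale (SE 0.19, adjusted p = 7.5e-05) and Hmga2 fell by 1.18 (SE 0.19). Egr1 was higher by 0.75 (SE 0.21, adjusted p = 0.0268), a call that the DESeq2 Wald test did not make. It was lost without control library A (adjusted p = 0.266), siRNA library A (0.0612) or siRNA library B (0.0654), and 0 negative regulators were higher in these fits. Of 15 markers of immature Schwann cells and neural crest, 3 rose, 4 fell and 8 did not pass, the same counts as adjusted over the list alone; without siRNA library B 2 were lower. Itga4 (0.76, SE 0.09) and the transcription factor gene Tfap2b (0.62, SE 0.10) rose, and the secreted signal gene Dhh (-0.69, SE 0.08) and Mcam (-0.43, SE 0.07) fell. This list gave no call (adjusted p = 0.981), and its signs differed, with a median of 0.05, a mean of 0.02, a higher direction by camera and a lower direction by fry.

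Genes that repair Schwann cells express after nerve injury were lower as a list. Of 20 tested members, 2 rose, 7 fell and 11 did not pass, the same counts as adjusted over the list alone, with a camera adjusted p = 0.0213 (adjusted p = 0.554 with an estimated correlation). Tgfa fell from 195.2 ± 0.326 to 111.5 ± 0.763 CPM (log2 fold change -0.81, SE 0.07, adjusted p = 2e-05). The phagocytic receptor gene Mertk fell by 0.78 on the log2 scale (SE 0.10) and the cytokine gene Clcf1 by 1.47 (SE 0.22). The members that rose, named after their values were seen, were Runx1 (0.35, SE 0.09) and Gfra1 (0.30, SE 0.09). The list's call was lost without siRNA library A (adjusted p = 0.0803) and without control library B (adjusted p = 0.0918). With either control library left out 1 member was higher, and with either siRNA library left out 0 were.

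Cholesterol synthesis genes fell and none rose in the edgeR test. Of 23 tested members, 10 fell and 13 did not pass (11 lower when adjusted over the list alone). At an unadjusted p under 0.05, 14 were lower and 0 higher, and DESeq2 called 10 lower and 0 higher. The median log2 fold change was -0.22 and the camera adjusted p = 6.35e-05 (adjusted p = 0.554 with an estimated correlation). Examples were the sterol carrier gene Stard4 (-0.66, SE 0.09, adjusted p = 0.000379) and the pathway enzyme genes Mvd (-0.53, SE 0.09), Lss (-0.46, SE 0.08) and Sc5d (-0.46, SE 0.08). Of 15 fatty acid synthesis genes, 3 rose, 1 fell and 11 did not pass (list adjusted p = 0.103; adjusted over the list alone, 4 higher and 1 lower). The phosphatidate phosphatase gene Lpin1 (0.87, SE 0.13) and the malic enzyme gene Me1 (0.52, SE 0.09) rose, and the acetyl-CoA synthetase gene Acss2 fell (-0.47, SE 0.10). The abundant desaturase gene Scd2 rose from 3699 ± 126 to 4337 ± 96.2 CPM (0.23, SE 0.07, adjusted p = 0.033). In this list 5 members were higher without control library A or with upper-quartile scaling, and 7 with library-size or loess scaling. The list was called higher without control library A (adjusted p = 0.0128) and with loess offsets (0.0151), both with the preset correlation; with all 4 libraries the adjusted p = 0.554 with an estimated correlation. Acss2 lost its call without siRNA library B (adjusted p = 0.0557), and Scd2 without control library B (0.114), siRNA library A (0.150) or siRNA library B (0.292).

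Extracellular matrix genes moved apart. Of 31 basal lamina and matrix genes, 10 rose, 6 fell and 15 did not pass (list adjusted p = 0.502; adjusted over the list alone, 13 higher and 7 lower). The thrombospondin gene Thbs1 fell from 1390 ± 23.9 to 836.1 ± 27.9 CPM (log2 fold change -0.73, SE 0.07, adjusted p = 2.34e-05), and Thbs2 fell from 157 ± 12.5 to 68.3 ± 1.23 CPM (adjusted p = 2.3e-06). The fibrillin gene Fbn1 (1.36, SE 0.14) and the basement membrane collagen gene Col18a1 (0.70, SE 0.08) rose. The list's median of -0.02 and mean of 0.10 differed in sign, and the median was above 0 with upper-quartile, library-size or loess scaling. Target genes of YAP and TEAD were lower as a list, with 3 of 21 higher, 6 lower and 12 not past (adjusted over the list alone, 3 higher and 7 lower; camera adjusted p = 0.0356; adjusted p = 0.554 with an estimated correlation). Ctgf, the gene of a matricellular factor, fell from 1374 ± 44.8 to 955.1 ± 29.2 CPM (-0.52, SE 0.07, adjusted p = 0.000308). Dock5 (-0.61, SE 0.08), Crim1 (-0.60, SE 0.08) and Amotl1 (-0.54, SE 0.09) fell too. The call of this list was lost without control library A (adjusted p = 0.0663), siRNA library A (0.0586) or siRNA library B (0.121), in each of which 1 member was higher. It was also lost with upper-quartile scaling (adjusted p = 0.0541), library-size scaling (0.0573), loess offsets (0.169), thinned counts (0.0517) or the 1 CPM filter (0.0631).

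Members of the TGF-beta and Notch lists went both ways. Of 19 TGF-beta response genes, 3 rose, 5 fell and 11 did not pass (list adjusted p = 0.835; adjusted over the list alone, 6 higher and 5 lower); with library-size scaling 6 were higher. Tgif1 (log2 fold change 0.85, SE 0.10, adjusted p = 0.000115) and the inhibitory Smad gene Smad6 (0.83, SE 0.13) rose, and Id1 (-0.84, SE 0.13) and Tagln (-0.52, SE 0.08) fell. Tagln overlaps Sidt2 on the same strand. Of 12 Notch pathway genes, 1 rose, 3 fell and 8 did not pass, the same counts as adjusted over the list alone (list adjusted p = 0.220). Notch2 rose (0.33, SE 0.08, adjusted p = 0.0107). Besides Hey2, which is also among the negative regulators, the ligand gene Jag1 (-0.25, SE 0.07, adjusted p = 0.0333) and the effector gene Hey1 (-0.58, SE 0.18, adjusted p = 0.0445) fell. Notch2 lost its call without control library B (adjusted p = 0.0721) or siRNA library A (0.0903), and Jag1 without control library A (0.156), siRNA library A (0.115) or siRNA library B (0.198). Hey1 lost its call without control library A (adjusted p = 0.128), control library B (0.130) or siRNA library A (0.196). Jag1 and Hey1 did not pass with upper-quartile or library-size scaling, where 1 member of the list was lower, nor did Jag1 with loess offsets, or Hey1 with DESeq2 or thinned counts. Without siRNA library A 0 Notch pathway genes were higher and 1 was lower, and without control library B 0 were higher.

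Nuclear receptor genes other than the targets moved in both directions. Of 27 tested members, 4 rose, 4 fell and 19 did not pass, the same counts as adjusted over the list alone (list adjusted p = 0.401). The vitamin D receptor gene Vdr rose from 4.64 ± 0.333 to 10.6 ± 0.517 CPM (adjusted p = 0.000581) and the thyroid hormone receptor gene Thrb rose by 0.74 on the log2 scale (SE 0.11). The retinoid X receptor gene Rxrg (-0.54, SE 0.10) and the circadian repressor gene Nr1d1 (-0.58, SE 0.11) fell, and Nr1d1 overlaps Thra on the other strand. Of 10 retinoid response and metabolism genes, 1 rose, 2 fell and 7 did not pass (list adjusted p = 0.921; adjusted over the list alone, 2 higher and 2 lower). The retinoic acid receptor gene Rarb, which is in both lists, fell (-0.95, SE 0.22, adjusted p = 0.011), as did Rdh10, whose enzyme makes retinal from retinol (-0.90, SE 0.12). Cyp26b1 rose as given above. The median of this list was 0.01 and its mean 0.07, while camera gave a lower direction; 2 members were higher with upper-quartile scaling, library-size scaling or limma-voom. Of 15 VEGF, neuropilin and angiopoietin genes, 2 rose, 3 fell and 10 did not pass, the same counts as adjusted over the list alone (list adjusted p = 0.331). The neuropilin genes went apart, with Nrp2 lower (-1.05, SE 0.08, adjusted p = 5.58e-06) and Nrp1 higher (0.54, SE 0.07, adjusted p = 0.000326). Vegfa fell from 120.7 ± 6.32 to 75.4 ± 0.190 CPM (-0.68, SE 0.08). Sema3f rose (1.14, SE 0.23) but lost its call without control library A (adjusted p = 0.0519), when 1 member was higher.

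Cell cycle genes fell together. Of 37 tested members, 33 fell, 0 rose and 4 did not pass in the edgeR test (34 lower when adjusted over the list alone), with a median log2 fold change of -0.44. At an unadjusted p under 0.05, 34 were lower and 0 higher, and DESeq2 called 32 lower and 0 higher. The camera adjusted p was 2.13e-26 (adjusted p = 0.338 with an estimated correlation). Rrm2, which encodes the regulatory subunit of ribonucleotide reductase, fell from 112.4 ± 11.7 to 57.6 ± 3.59 CPM (-0.97, SE 0.09, adjusted p = 3.36e-05), and the replicative helicase gene Mcm5 from 172.8 ± 2.60 to 100.9 ± 7.28 CPM (-0.78, SE 0.08). The mitotic ubiquitin-conjugating enzyme gene Ube2c fell by 0.70 on the log2 scale (SE 0.09) and the transcription factor gene E2f1 by 0.76 (SE 0.10); E2f1 overlaps RGD1561517 and Actl10 on the other strand. Of 18 p53 targets, 1 rose, 3 fell and 14 did not pass, the same counts as adjusted over the list alone (list adjusted p = 0.377). Plk2 (-0.64, SE 0.07, adjusted p = 0.000129), Rrm2b (-0.90, SE 0.16) and Gadd45a (-0.47, SE 0.11) fell and Tp53inp1 rose (0.53, SE 0.12). Gadd45a lost its call without control library B (adjusted p = 0.0917) and Tp53inp1 without siRNA library B (adjusted p = 0.157), when 0 targets were higher.

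Single members of the stress and interferon lists changed in both directions. Of 24 genes of the unfolded protein and integrated stress responses, 2 rose, 6 fell and 16 did not pass (list adjusted p = 0.0622; adjusted over the list alone, 2 higher and 9 lower). With either siRNA library left out 3 were lower. The list was called lower without control library A (adjusted p = 0.0222), with limma-voom (0.0361) and without the filter on low counts (0.0210), all with the preset correlation; with all 4 libraries the adjusted p = 0.554 with an estimated correlation. Ppp1r15a, encoding the phosphatase subunit GADD34, fell from 166.4 ± 3.42 to 96.7 ± 10.6 CPM (log2 fold change -0.79, SE 0.09, adjusted p = 9.55e-05) and Atf4 fell (-0.35, SE 0.07), while Ddit4 (0.73, SE 0.12) and the chaperone gene Dnajb9 (0.66, SE 0.12) rose. Of 19 interferon response genes, 2 rose, 2 fell and 15 did not pass, the same counts as adjusted over the list alone (list adjusted p = 0.721). Gbp2 fell from 76.5 ± 3.77 to 28.0 ± 1.82 CPM (-1.44, SE 0.09, adjusted p = 1.36e-06) and Mx2 fell (-1.63, SE 0.50, adjusted p = 0.0385), while Ifi44 (0.67, SE 0.13) and Stat2 (0.30, SE 0.08) rose. The list's median of 0.01 and mean of -0.14 differed in sign, and the median was -0.06 with loess offsets. Mx2 was at -0.79 without control library A (adjusted p = 0.548), lost its call without siRNA library A (0.0523) or B (0.155), and was not called by DESeq2, limma-voom or with thinned counts. Ifi44 lost its call without siRNA library B (adjusted p = 0.0569), and Stat2 without control library A (0.109), siRNA library A (0.104) or siRNA library B (0.0936). Without control library A or siRNA library A 1 interferon response gene was higher and 1 lower, and without siRNA library B 0 were higher and 1 was lower.

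Of 16 NF-kB and inflammatory genes, 1 rose, 2 fell and 13 did not pass, the same counts as adjusted over the list alone (list adjusted p = 0.808). The chemokine gene Ccl2 fell from 11.3 ± 0.219 to 6.83 ± 0.125 CPM (log2 fold change -0.72, SE 0.15, adjusted p = 0.00657), Tnfaip3 fell (-0.68, SE 0.19) and Il1rl1 rose (0.46, SE 0.12). Tnfaip3 lost its call with DESeq2 and when any 1 library was left out, with an adjusted p = 0.0647 without control library A, 0.134 without control library B, 0.0549 without siRNA library A and 0.161 without siRNA library B. Il1rl1 lost its call without control library A (adjusted p = 0.151) or siRNA library B (0.0718), when 0 members were higher, and 1 was lower without control library B, without siRNA library B or with DESeq2. Of 19 glycolysis and hypoxia response genes, 1 rose, 5 fell and 13 did not pass, the same counts as adjusted over the list alone (list adjusted p = 0.129), and the median of -0.15 and the mean of 0.03 differed in sign. Besides Vegfa, which is in the VEGF list too, the glycolytic enzyme genes Aldoa (-0.33, SE 0.07) and Gapdh (-0.31, SE 0.07) fell. Adm, the gene of adrenomedullin, rose by 3.02 on the log2 scale (SE 0.72, adjusted p = 0.0116), from 7 counts in the control libraries to 87 in the siRNA libraries, a rate ratio of 8.39 (95% exact interval 3.91 to 21.5). Without siRNA library B 1 member was lower, Aldoa (adjusted p = 0.0583) and Gapdh (0.0960) lost their calls, and Adm was at 2.09 (0.168). Without control library B 3 members were lower, and Adm also lost its call without control library A (adjusted p = 0.0790) or B (0.0517). With DESeq2 or the 1 CPM filter 0 members were higher. The glycolysis list was called lower without control library A (adjusted p = 0.0398) with the preset correlation; with all 4 libraries the adjusted p = 0.554 with an estimated correlation.

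Among markers of other cell types, neurofilament genes fell and few others passed the test. Of 10 fibroblast and perineurial markers, 0 rose, 0 fell and 10 did not pass in the edgeR test, also when adjusted over the list alone (list adjusted p = 0.483). At an unadjusted p under 0.05, 2 were higher and 0 lower, and DESeq2 called 1 higher and 0 lower; with library-size or upper-quartile scaling edgeR called 2 higher. The most abundant were Col1a1 (log2 fold change -0.02, adjusted p = 0.87, above 0 with upper-quartile, library-size or loess scaling) and Col3a1 (0.20, adjusted p = 0.0611), which are in the matrix list too. Col3a1 passed as higher with upper-quartile, library-size or loess scaling, DESeq2 or limma-voom. Of 5 macrophage markers, Laptm5 rose (2.55, SE 0.64, adjusted p = 0.0157) and 4 did not pass (list adjusted p = 0.331). Laptm5 had 7 counts in the control libraries and 62 in the siRNA libraries, a rate ratio of 5.98 (95% exact interval 2.74 to 15.5). Of 5 melanocyte markers, Dct (2.52, SE 0.56, adjusted p = 0.00854) and Mitf (0.50, SE 0.15) rose, Pmel (-0.38, SE 0.10) fell and 2 did not pass (list adjusted p = 0.401). Dct had 10 and 86 counts, a rate ratio of 5.81 (95% exact interval 3.01 to 12.5), and Pmel overlaps Dgka on the other strand.

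Of 5 neuron markers, the neurofilament genes Nefl (log2 fold change -2.10, SE 0.09, adjusted p = 2.55e-08) and Nefm (-1.18, SE 0.15, adjusted p = 0.000224) fell, Tubb3 rose (0.31, SE 0.10) and 2 did not pass. This list was lower by camera (adjusted p = 0.00022; adjusted p = 0.554 with an estimated correlation), but not with limma-voom (adjusted p = 0.286). Its median of 0.11 and mean of -0.38 differed in sign. The median was below 0 with loess offsets (-0.13), DESeq2 (-0.009), no filter (-0.053), the 1 CPM filter (-1.18) or thinned counts (-0.62). It was also below 0 without control library A (-0.47) or siRNA library B (-0.37). For the macrophage, melanocyte and neuron lists the counts adjusted over the list alone were the same as those given. Laptm5 lost its call without control library A (adjusted p = 0.162) or B (0.0709), and Dct without control library A (0.0670) or B (0.0561). Mitf lost its call without control library A (adjusted p = 0.120), control library B (0.0880) or siRNA library B (0.342), and with DESeq2 or thinned counts. Pmel lost its call without control library A (adjusted p = 0.177) or siRNA library B (0.210), and Tubb3 without control library A (0.169), control library B (0.0749) or siRNA library A (0.365). Without siRNA library A 2 macrophage markers were higher, and 0 were with DESeq2 or the 1 CPM filter. Without control library A 0 melanocyte markers were higher or lower, and 1 was higher with DESeq2, thinned counts or protein-coding genes alone.

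**Figure D4:**
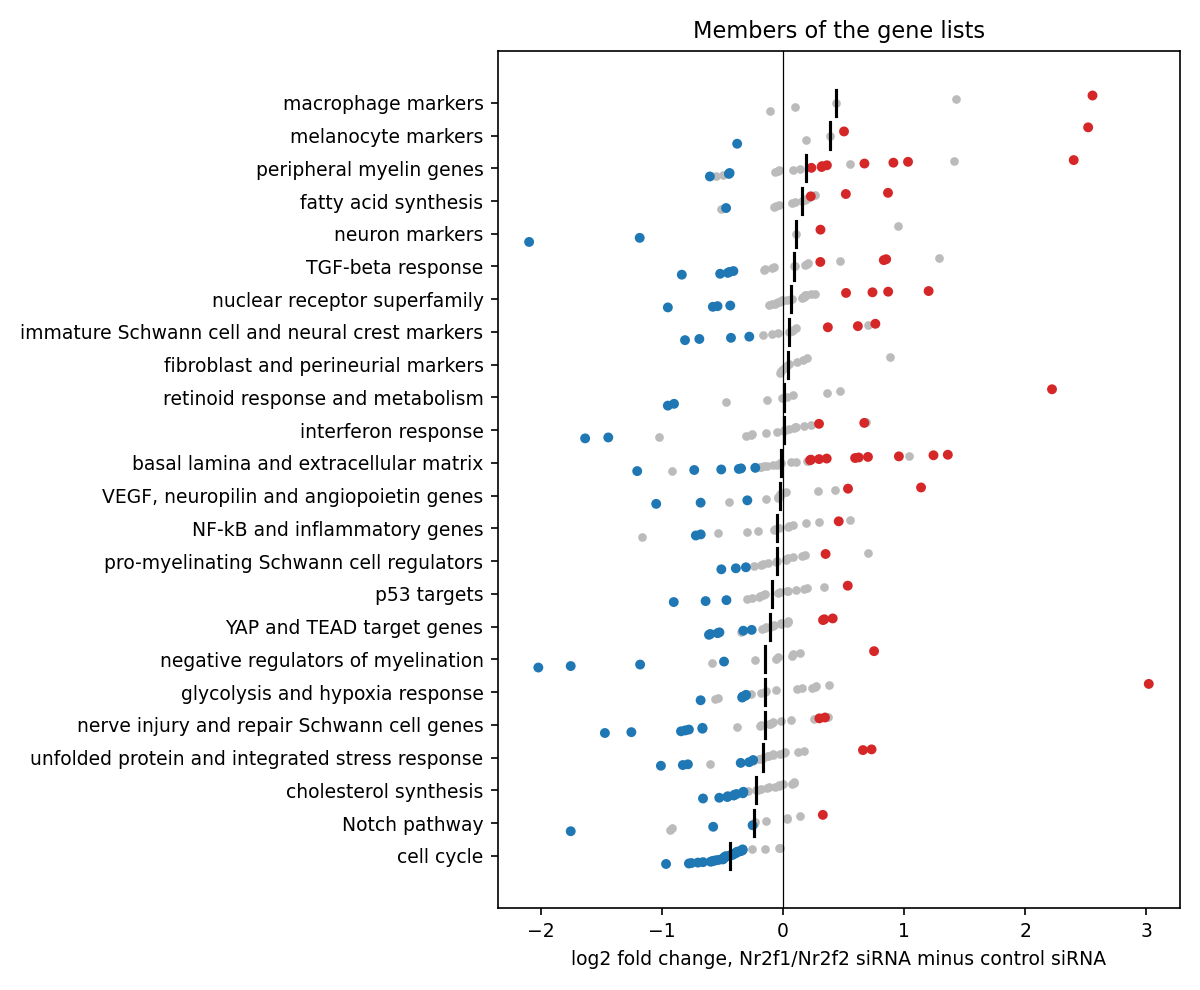
Log2 fold change, Nr2f1/Nr2f2 siRNA minus control siRNA, of the tested members of 24 gene lists; red and blue points are members that were higher or lower with an adjusted p under 0.05, grey points did not pass, and black ticks are list medians. The cell cycle list has the lowest median at -0.44 with 33 of 37 members lower; the medians of the matrix, interferon, fibroblast and neuron lists change sign with loess offsets, and those of the matrix, VEGF, pro-myelinating and NF-kB lists lie so near 0 that the shift of all genes under library-size scaling (0.052) turns their sign, as that under upper-quartile scaling (0.034) does for the matrix and VEGF lists.

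By camera with the preset correlation 6 of the 24 lists passed, 5 lower and 1 higher. With a correlation estimated from these libraries 0 lists passed and the smallest adjusted p was 0.338, for the cell cycle list, which was the 1 list with an unadjusted p under 0.05. That test has few degrees of freedom with these libraries, so its losses cannot tell whether correlation between genes undoes the calls. For the myelin and repair lists the estimated correlation (-0.012 and -0.0044) was below the preset 0.01, and their calls were lost all the same. The estimate was above the preset for the cholesterol (0.194), YAP and TEAD (0.187), neuron (0.090) and cell cycle (0.038) lists. For these lists the p-values of camera with the preset correlation may be too small. Fry, a rotation test of whether the genes of a list move on balance in 1 direction, called 2 lists lower. These were the cell cycle genes and the VEGF, neuropilin and angiopoietin genes, both with an adjusted p = 0.0303; the median of the second list, -0.03, was above 0 with upper-quartile or library-size scaling, by the shift these give all genes.

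The authors' deposited table holds their own comparison of the same libraries, so it is not independent of the values above. At an adjusted p under 0.05 the authors' deposited table held 1986 genes, 792 higher and 1194 lower. Of the genes called in the authors' deposited table, 1889 (95.1%) were called in the same direction by edgeR, 770 higher and 1119 lower, and 0 were called in the opposite direction. A further 461 genes were called by edgeR alone and 97 in the authors' deposited table alone. Among the genes edgeR called, 99.2% had a log2 fold change within 0.1 of that in the authors' deposited table, where Nr2f1 is at -1.89 and Nr2f2 at -2.04.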

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

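Thinning and loess offsets were chosen after seeing the data; the other alternatives were set before. No paired analysis was possible because the numbers in the column names of the 2 groups share only 1 value: 3 is in both, 1 in the control group alone and 2 in the siRNA group alone. What these numbers mark is not given in the sources used here. Camera was not run on the DESeq2 fit. With a library left out, the lone library of its group is assumed to vary like the other group. The number of called genes was 2350. Under alternatives of scaling, filter, test and gene set it stayed within 1.5 times that number, from 2078 with DESeq2 to 2536 with limma-voom. Fewer genes pass stricter thresholds by construction: 1125 (455 higher, 670 lower) at an adjusted p under 0.01, and 289 (175 higher, 114 lower) with at least a 2-fold change; 200 genes had a 2-fold change here and in the authors' deposited table. Leave-one-out fits, with fewer samples, called 1353 to 1813 genes, 602 to 766 higher and 751 to 1086 lower.

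Of the changes of named genes, 1169 of the values under other settings kept their direction and side of the threshold, 16 were weaker, 5 passed where they had not and 3 changed sign. In leave-one-out fits 381 kept both, 54 were weaker and 1 changed sign. The knockdown of Nr2f1 and Nr2f2 passed in all of these. The sign changes were those of Col1a1, from -0.02 to 0.013 with upper-quartile, 0.032 with library-size and 0.063 with loess scaling, and -0.058 to 0.0059 in leave-one-out fits, above 0 without control library A alone. Upper-quartile and library-size scaling shift all genes nearly alike, their median by 0.034 and 0.052, which by construction turns a value so near 0; the cause of the other sign changes was not tested.

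The number of called lists, 6, was 0 with an estimated correlation, 2 with fry, 3 with the filter of 1 CPM in 2 libraries and 3 with thinned counts. Under the last 2 the neuron list had too few members to test. With an estimated correlation camera had few degrees of freedom with these libraries, so its losses do not decide on the calls. The cause of the other losses was not tested. Directions of uncalled lists also turned, with the cause not tested. For immature Schwann cell markers they did so with fry (adjusted p = 0.764), DESeq2 size factors (0.995), no filter (0.975), the 1 CPM filter (0.996), limma-voom (0.889) and without control library B (0.917) or siRNA library A (0.950), within 0.825 to 0.959 over the 4 leave-one-out fits. For retinoid genes they turned with limma-voom (adjusted p = 0.993) and without control library B or siRNA library A, the second with the highest adjusted p of the 4 leave-one-out fits (0.931, the lowest being 0.572), for interferon genes with limma-voom (0.955), and for NF-kB genes with the 1 CPM filter (0.996) and without control library B (0.917, the highest of the 4 fits, the lowest being 0.572). For matrix genes they turned without control library B alone (adjusted p = 0.996; 0.353 to 0.996 over the 4 fits). For TGF-beta genes they turned without control library A (adjusted p = 0.959) or siRNA library A (0.746), with 0.440 to 0.959 over the 4 fits. Depth limits the weak genes: with 7 counts in the control libraries, the interval of the rate ratio of Adm runs from 3.91 to 21.5.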

Other observations

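The tests of the chromosome 1 neighbours, of Lamp1 against Nr2f2 and of protein-domain families, tubulins included, were chosen after the result was seen, as was the protocadherin beta family. Some protein-domain families held more genes that fell than a random draw not matched for expression level gives. Of 304 tests of 152 domain families in each direction, against 5721 tested genes with a family, 5 passed, all lower. Abundant genes were called lower more often, 418 of 2220 above 100 CPM against 12 of 1237 at or below 1 CPM. The p-values may therefore be too small for families of abundant genes, and a draw matched for level was not made. Of 17 tubulin genes, 11 fell, 1 rose and 5 did not pass (adjusted p = 7.31e-05 for the number lower, hypergeometric test), with 9 to 11 lower across the other settings. Tuba1b fell from 1223 to 718.1 CPM (log2 fold change -0.77, SE 0.07) and Tubb5 from 1638 to 1153 CPM (-0.51, SE 0.07), while the neuronal Tubb3 rose. Tubulin genes share sequence, so single values are uncertain. Both gene IDs with the symbol Tuba1c are among those that fell. The hypergeometric test treats genes that share reads as independent, so its p-value may be too small for this reason too. Of 37 kinesin genes, 13 fell and 4 rose (adjusted p = 0.0123), with Kif19 (-0.92), Kifc1 (-0.55) and Kif4a (-0.55) among those that fell; 8 fell without control library A, siRNA library A or siRNA library B. Of 48 genes with a calponin homology domain, 16 fell and 2 rose (adjusted p = 0.00652), among them Flnc (-0.74), Flna (-0.32) and Iqgap3 (-0.74), and 10 fell without siRNA library B. Of 13 genes with a C-terminal cyclin domain, 7 fell and 1 rose (adjusted p = 0.0165), among them Ccnd3 (-0.67) and Ccnd1 (-0.48). The kinesin and cyclin families moved with the cell cycle list, of whose 37 members 33 fell: 3 kinesin genes that fell and 4 cyclin genes that fell are in that list, and Kifc1 and Kif4a encode mitotic motors too. With the members of the list left out, neither family passed. Of the kinesin genes left, 10 of 34 were lower (adjusted p = 0.194, unadjusted p = 0.00255, hypergeometric test). Of the cyclin genes left, 3 of 8 were lower (adjusted p = 0.689, unadjusted p = 0.0476, hypergeometric test). Leaving out members that mostly fell weakens the enrichment by construction, so this does not show that the list carries it. Of 11 genes with a von Willebrand factor C domain, 6 fell, such as Nov (-0.81), and Chrd rose (1.22) (adjusted p = 0.0354), with 3 lower without siRNA library B. Across the other settings with all libraries, 2 to 4 genes with a calponin homology domain, 3 to 4 kinesin genes, 1 to 2 cyclin genes and 1 tubulin gene were higher. The median of each of the 5 families stayed below 0 there and in leave-one-out fits. For the calponin homology family it lay near 0, at -0.072, and at -0.020 with library-size scaling and -0.021 with loess offsets. For the tubulin family it was -0.50.

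Protocadherin beta genes on chromosome 18 (30375798 to 30595181) had higher fitted values together. All 18 tested genes had a log2 fold change above 0, with a median of 0.49 (0.29 with loess offsets), and 3 passed the test, Pcdhb15, Pcdhb17 and Pcdhb21. Over all tested genes, 1048 of 13018 were called higher. The family is weakly expressed, with 11 genes left by the filter of 1 CPM in 2 libraries. Weak genes had higher fitted values in general, with a median of 0.19 at or below 1 CPM. Without control library A 1 passed, and with any other library left out 2 passed. The family was singled out after its values were seen, and the wider cadherin domain family did not pass, with 12 of 53 genes higher (adjusted p = 0.175, hypergeometric test). These genes share sequence, so the assignment of reads among them is uncertain.

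Neighbouring genes on chromosome 1 fell together: in the window of 15 tested genes from Plce1 to AABR07072054.1 (257157264 to 259981938) the median was -0.86, 7 genes were lower and 0 higher, and 6 of the 7 fell at least 2-fold. The permutation p was 0.0001 for the median and for the count of such genes, the smallest that the shuffles can give, but without AC096370.2, the near copy of Aldh18a1, the lowest median there was -0.32 (permutation p = 0.8808). The count was chosen only after the median without the copy had been seen, on genes already seen to fall. It therefore cannot decide on random placement. Without the copy a window there held 5 genes at least 2-fold lower (permutation p = 0.0005). Without AC096370.2, AABR07006774.1 and AABR07072054.1 it held 4 (permutation p = 0.0215), with LOC100912537 left in. A window on chromosome 2 with Gbp2, Gbp4 and Gbp5 held 4 as well. Reads moved between the copies are argued against, since the log2 ratio of their summed CPM was -3.30 (23.8 to 2.41 CPM). Random placement and other explanations, biological ones included, stay open for these neighbours.

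Lamp1 fell by 1.95 on the log2 scale, as far as the siRNA targets. A shared fall of lysosomal genes is argued against: the median of 28 other lysosomal genes was 0.10 (SE of the mean 0.04), with 8 higher and 0 lower by edgeR (1 lower at an unadjusted p under 0.05, and 0 lower by DESeq2), and the lowest, Sqstm1, was at -0.23. An unintended target of one of the siRNAs may account for it, and the log2 fold change of Lamp1 minus that of Nr2f2 was 0.082 (SE 0.11). With a single pair of siRNAs this cannot be told apart from a response to the lowered receptors. Besides the targets, Adamts15, Nefl and Adamts9 fell as far among genes with at least 50 CPM in control.

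Cell cycle genes were lower in 33 of 37 cases (camera adjusted p = 2.13e-26, 1.08e-34 to 0.338 over the alternatives). A trend of the log2 fold change with expression level is argued against, since with loess offsets the median was -0.42 (SE of the mean 0.03). The difference in depth is argued against too, since 32 members were lower after thinning to the shallowest library. A response to the lowered receptors and a difference in growth or density between the cultures were not tested and stay open, since cell counts, matched densities and another pair of siRNAs were not analysed here.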
